A study of Mus musculus with 32 samples.

How the data were processed

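The arrays measured RNA from the cerebrum and the spinal cord of male C57BL/6J mice, at control and 1, 3 and 7 days after photothrombosis. Per the labels, tissue was snap frozen, RNA was extracted with TRIzol, and 10 ng of total RNA was labelled with biotin. The summarisation method, software and build of the authors are not given in the sources used here. The deposited values are log2 values, of which the lowest is -5.582 and the highest 8.042, and the array medians run from -0.0553 to 0.0333. No value is exactly 0, and the number of arrays limits the precision.

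The deposited values were found to be centred per probe in 3 parts. The 16 arrays of controls and day 1 have a median of 0 in 100% of probes, so they were centred together. The 8 arrays of day 3 and the 8 of day 7 were each centred apart. With the 8 controls as partners, centring matched in 86.8% of 5613 and 86.4% of 5123 probes tested, against 54.1% to 71.9% for others. The offset of each probe between parts was therefore rebuilt from this match. It was fixed to a single value in 78.1% of probes for day 3 and 80.1% for day 7, and was otherwise a range. The median absolute offset was 0.0718 and 0.0923. An allowance of 0.172 and 0.177 was added for other processing differences between the parts. A gene compared across parts had to exceed the range's half-width plus this allowance, by limma's test against a bound. Comparisons within a part and the spinal-minus-cerebral differences, in which the offset drops out, were tested against 0. The planned fit used the values as deposited, and the rebuilt offset replaced it after the centring was seen. The tests of gene lists use the rebuilt values with no bound.

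Of 22206 probes, 19572 carry 1 gene symbol in the GRCm38.p6 annotation used, which gives 19505 genes, 55 of them with several probes. A gene's value is the mean of its probes. The planned rule, the probe with the highest mean, became the alternative, since centred values carry no level. The 2634 probes with no symbol were fitted apart. Groups were taken from the labels, and replicate numbers follow the order of deposition and pair nothing. All 32 arrays entered 1 limma fit with 8 group means and 24 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 was called changed. There were 12 comparisons, each day against control in each tissue, the spinal-minus-cerebral difference of these at each day, day 7 against day 1 in each tissue, and the control groups against each other. Tools were R 4.3.3 with limma 3.58.1 and matrixStats 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

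The 28 gene lists, the comparisons, the rule for named genes and the alternatives not named below as later were chosen before the data were examined. The lists are homeostatic microglia, activated phagocytic microglia, monocytes and macrophages, neutrophils, lymphocytes, oligodendrocyte precursors, myelin and mature oligodendrocytes, homeostatic astrocytes, reactive astrocytes, neurons, endothelial cells, fibroblasts and extracellular matrix, cell cycle, type I interferon response, inflammatory cytokines and chemokines, complement, antigen presentation by MHC class II, hypoxia response, immediate early genes, cholesterol synthesis, lipid uptake, storage and efflux, growth factors acting on oligodendroglia, Schwann cells, choroid plexus, skeletal muscle, red blood cells, forebrain identity and Hox genes of the trunk. They hold 418 different genes, of which 377 were measured. Each list was tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over all lists and comparisons, and with fry, which asks whether a list's genes move 1 way on balance. Of 183 calls at the preset correlation, 23 held with an estimated one, and the text names these.

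Named genes are the 10 largest rises and 10 largest falls with an adjusted p under 0.05 in each comparison with control whose 4 injured arrays all lie beyond all 4 controls. For the differences between tissues they are the 5 largest each way, and for the controls the 10 largest each way, with no condition on overlap. Members of the lists may be named in any comparison, and only they are named for day 7 against day 1. Predicted genes were passed over. Lists of thalamus and striatum genes were written after the values had been seen, but before their own values were.

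The fit was tested on simulated data with the same centring. With no effect it gave 0 calls in each of 11 comparisons. Of 50 genes changed by 0.5 and 50 by 1, 54% and 92% were called for spinal day 1. The shares were 22% and 92% for day 3 and 20% and 80% for day 7. For the differences these shares were 18% and 72% at day 1, 14% and 86% at day 3 and 4% and 72% at day 7. At most 9 of 181 calls were false, and 0 had the wrong sign. Far more genes changed in the data, so these rates may not hold there.

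Alternatives planned and run were quantile normalisation on top of the values, 75th percentile scaling, the other probe rule, a fit of only the compared groups, array weights, an estimated correlation for the lists, and leaving out each array in turn. Alternatives chosen after seeing the data were the values as deposited, the rebuilt offset taken as exact, the allowance as a bound for the differences, median scaling, a robust prior alone, spinal controls 3 and 4 only, cerebral controls 3 and 4 only and cerebral controls 1 and 2 only.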

Results

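Gene expression was measured on 32 arrays of RNA from the cerebrum and the spinal cord of mice with photothrombotic ischaemia, an injury in which light closes vessels that carry a photosensitive dye. Each tissue had 4 control arrays and 4 arrays each from day 1, day 3 and day 7, which makes 8 groups of 4. The labels do not say whether the controls had surgery. The p-values measure the spread between these samples, since the labels do not say that each came from a separate animal. The number of arrays limits the precision. Expression of 19505 genes was tested, the median residual SD was 0.185 on the log2 scale, and the median SD within a group ran from 0.138 at cerebral day 3 to 0.207 at spinal day 3. Spinal day 3 replicate 1 stood apart, with an array weight of 0.225 and an SD over genes of 0.675. The sample titles of each group carry numbers from a range of their own, so if these ranges mark batches, batch and group cannot be told apart.

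All changes are log2 differences between group means with their SE from the limma fit, and n = 4 arrays per group throughout. The day 3 and day 7 arrays were centred apart from the controls, so their differences from control rest on a rebuilt offset per probe, whose uncertainty is part of each gene's test but not of the tests of gene groups. In the GRCm38.p6 annotation, the genes plotted array by array are P2ry12 (Entrez identifier 70839) on chromosome 3 from 59216271 to 59262985, Gpnmb (93695) on chromosome 6 from 49036518 to 49058182, and Gfap (14580) on chromosome 11 from 102887336 to 102897200. Mbp (17196) lies on chromosome 18 from 82475091 to 82585637, Egr1 (13653) on chromosome 18 from 34861207 to 34864956, and Arg1 (11846) on chromosome 10 from 24915207 to 24927470.

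**Figure D1:**
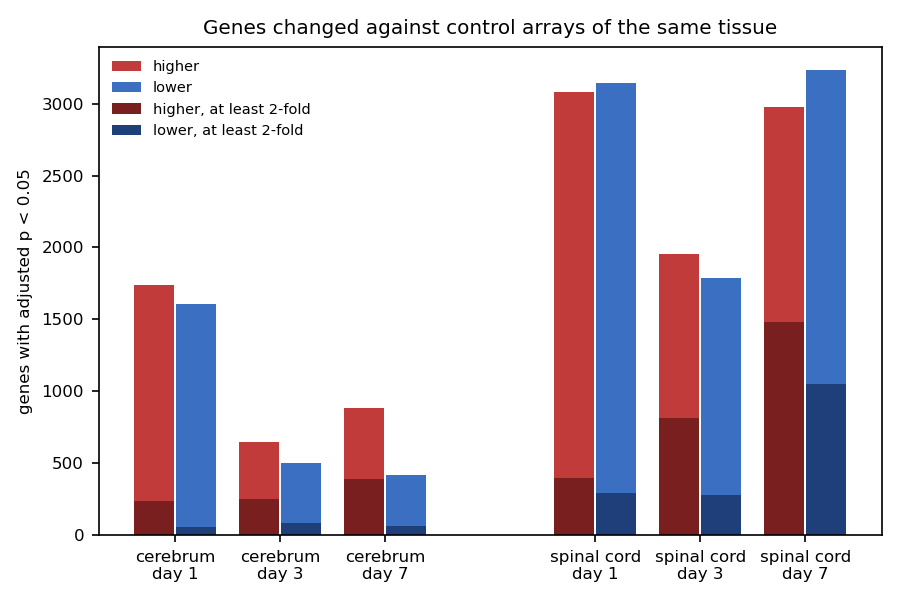
Number of genes with an adjusted p under 0.05 at each day against the control arrays of the same tissue (vertical axis), higher and lower shown apart, with the part changed at least 2-fold in the darker shade. Spinal day 7 had 6207 changed genes against control and cerebral day 7 had 1295.

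The control groups were compared to ask how the tissues differed without the injury. Spinal controls were above cerebral controls in Glra1, a glycine receptor subunit (log2 6.54 ± 0.28), Slc6a5, the neuronal glycine transporter (6.25 ± 0.21), and the homeobox genes Hoxc8 (5.79 ± 0.24) and Hoxb9 (5.56 ± 0.21), which set trunk identity. Klk6, a protease of oligodendrocytes, Prph, the filament protein peripherin, Sncg, a synuclein, and the transcription factor Ebf3 were also among the 10 largest rises, at 6.06, 4.83, 4.60 and 5.17. Spinal controls were lower in Slc17a7, the vesicular glutamate transporter of cortical neurons (-6.12 ± 0.31), Ttr, a product of the choroid plexus (-6.02 ± 0.23), and Tbr1, a transcription factor of cortical neurons (-4.60 ± 0.15). Ddn, Chrm1, Itpka, Mef2c, Drd1, Nrgn and Rasgrp1, all expressed in forebrain neurons, were lower by log2 values from -6.39 for Ddn to -4.56 for Rasgrp1. Adjusted p in limma ran from 1.45e-21 to 6.87e-06 for these genes and for Myh4 and Atp2a1 of fast skeletal muscle, at 5.47 ± 0.88 and 5.25 ± 0.76.

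All 17 measured genes of myelin and mature oligodendrocytes were higher in the spinal controls (mean log2 change 2.22, adjusted p = 5e-19, and adjusted p = 0.0393 with an estimated correlation), among them Ermn at 3.38, Mbp at 2.59 and Mog at 2.25. Cholesterol synthesis had 12 higher, 0 lower and 1 not passed (mean log2 change 1.13, adjusted p = 3.97e-10, or 0.0521 with an estimated correlation). Of 16 Hox genes of the trunk, 14 were higher (mean log2 change 2.46, adjusted p = 8.16e-18, or 0.00397 with an estimated correlation). Of 10 genes of forebrain identity, 9 were lower (mean log2 change -2.49, adjusted p = 1.38e-12, or 0.00972 with an estimated correlation). Immediate early genes, which respond within minutes to neuronal activity, had 0 higher, 11 lower and 4 not passed (mean log2 change -1.43, adjusted p = 2.16e-06, or 0.1 with an estimated correlation). Egr1 stood at -3.40. The choroid plexus list had 0 higher, 8 lower and 4 not passed (mean log2 change -0.99, adjusted p = 0.000118, or 0.1 with an estimated correlation). All 12 skeletal muscle genes were higher in the spinal controls (mean log2 change 2.23, adjusted p = 2.16e-06, and adjusted p = 0.261 with an estimated correlation). Their mean was 0.926 with spinal controls 3 and 4 only, with Myh4 at 2.79 and Atp2a1 at 3.08. The muscle score was 3.62, 3.04, 1.21 and 0.24 in spinal control replicates 1 to 4. Myelin had 17 higher and 0 lower adjusted over the list alone, cholesterol synthesis 12 and 0, Hox genes 14 and 0, forebrain identity 0 and 9, immediate early genes 0 and 11, choroid plexus 1 and 8 and muscle 12 and 0. In all, 6778 genes differed, 3352 higher and 3426 lower in the spinal controls.

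Cerebral day 1 was compared with cerebral control to ask what changed early after the brain injury. Mmp12, a macrophage elastase, rose 48.6-fold (log2 5.60 ± 0.39, SE), Lcn2, a siderophore-binding protein of reactive astrocytes, 22-fold (4.46 ± 0.73), and Gfap, the intermediate filament of astrocytes, 12.1-fold (3.60 ± 0.26). Serpina3n, a serine protease inhibitor, Tgm1, a transglutaminase, Plin2, a coat protein of lipid droplets, Mpeg1, a pore-forming protein of macrophages, Bcl2a1b, a survival factor of the Bcl2 family, and the proliferation genes Mki67 and Pbk completed the 10 largest rises, from 3.66 to 2.90. Adjusted p over the 10 ran from 2.46e-13 to 7.82e-05. The largest falls were in Prl, the hormone prolactin (-2.98 ± 0.51), and the activity-dependent genes Nr4a1 (-2.17 ± 0.25) and Egr1 (-1.94 ± 0.30). Pomc, a hormone precursor, the neuropeptide Npy, the postsynaptic protein Nrgn, Dtx3 and the olfactory receptors Olfr731, Olfr1170 and Olfr1110 fell by 1.35 to 1.89. With quantile normalisation on top, Mmp12 stood at 7.29, Gfap at 2.89, Tgm1 at 4.75, Mpeg1 at 4.87, Mki67 at 4.84, Pbk at 4.28 and Prl at -4.21. In the cerebral controls, Prl ran from 1.53 to 4.77 and Pomc from 0.481 to 2.64. Pmch, a hypothalamic peptide gene outside the named genes, read 6.62, 6.75, 0.156 and 0.0153 in control replicates 1 to 4. Injured samples varied too. Pmch ran from 1.74 to 3.89 at cerebral day 1 and from 3.73 to 9.45 at day 7, where Prl ran from -0.0805 to 3.74.

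Genes of activated phagocytic microglia had 12 higher, 0 lower and 4 not passed (mean log2 change 1.11, adjusted p = 1.14e-12, or 0.0504 with an estimated correlation). Gpnmb stood at 2.29, Ctsz at 2.12 and Tyrobp at 1.87. Homeostatic microglia had 6 higher, 0 lower and 6 not passed (mean log2 change 0.71, adjusted p = 4.69e-05, or 0.266 with an estimated correlation). Csf1r, the receptor that microglia need to survive, stood at 1.87, while P2ry12, a purine receptor of resting microglia, read 0.15 ± 0.25 and did not pass. Complement genes had 7 higher, 0 lower and 4 not passed and held their call both ways (mean log2 change 1.18, adjusted p = 4.83e-10, or 0.0372 with an estimated correlation). C1qa stood at 2.32. Reactive astrocytes had 9 higher, 0 lower and 6 not passed (mean log2 change 1.46, adjusted p = 7.61e-11, or 0.0675 with an estimated correlation). Cell cycle genes had 15 higher, 0 lower and 2 not passed (mean log2 change 1.08, adjusted p = 8.03e-15, or 0.0675 with an estimated correlation). Endothelial cells had 5 higher, 0 lower and 9 not passed (mean log2 change 0.48, adjusted p = 1.87e-05, or 0.0382 with an estimated correlation). Immediate early genes had 1 higher, 7 lower and 7 not passed (mean log2 change -0.63, adjusted p = 0.000409, or 0.242 with an estimated correlation). Arc stood at -1.14 against Atf3, a stress-induced factor, at 0.88. Activated microglia had 13 higher and 0 lower adjusted over the list alone, homeostatic microglia 7 and 0, complement 7 and 0, reactive astrocytes 10 and 0, cell cycle 17 and 0, endothelial cells 9 and 0 and immediate early genes 1 and 7.

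Myelin genes had 9 higher, 0 lower and 8 not passed at cerebral day 1, 9 higher and 0 lower adjusted over the list alone (mean log2 change 0.50, adjusted p = 2.16e-06, or 0.251 with an estimated correlation). Trf stood at 1.33, Bcas1 at 0.97 and Mbp at 0.58 ± 0.11. Slc17a6, the glutamate transporter of subcortical neurons, rose by 1.28, and 9 of 14 marker genes of the thalamus were higher and 0 lower in the same samples (mean log2 change 0.83). Forebrain identity had 0 higher, 4 lower and 6 not passed, 0 higher and 4 lower adjusted over the list alone (mean log2 change -0.37, adjusted p = 0.0094, or 0.251 with an estimated correlation). In all, 3341 genes changed, 1737 higher and 1604 lower. The count was 5256 with quantile normalisation on top, which also ended the myelin call (mean log2 change 0.177, adjusted p = 0.199, with 1.33e-10 to 0.251 over its alternatives) and the forebrain call (-0.261, 0.306, with 0.000339 to 0.306). With cerebral controls 3 and 4 only or 1 and 2 only, choices made after seeing the data, it was 2115 and 1719, and with controls 1 and 2 only the forebrain call was lost (-0.206, adjusted p = 0.145), myelin stood at 0.271, Prl at -1.85 and Pomc at -1.06, against -2.37 for Pomc with 3 and 4 only.

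**Figure D2:**
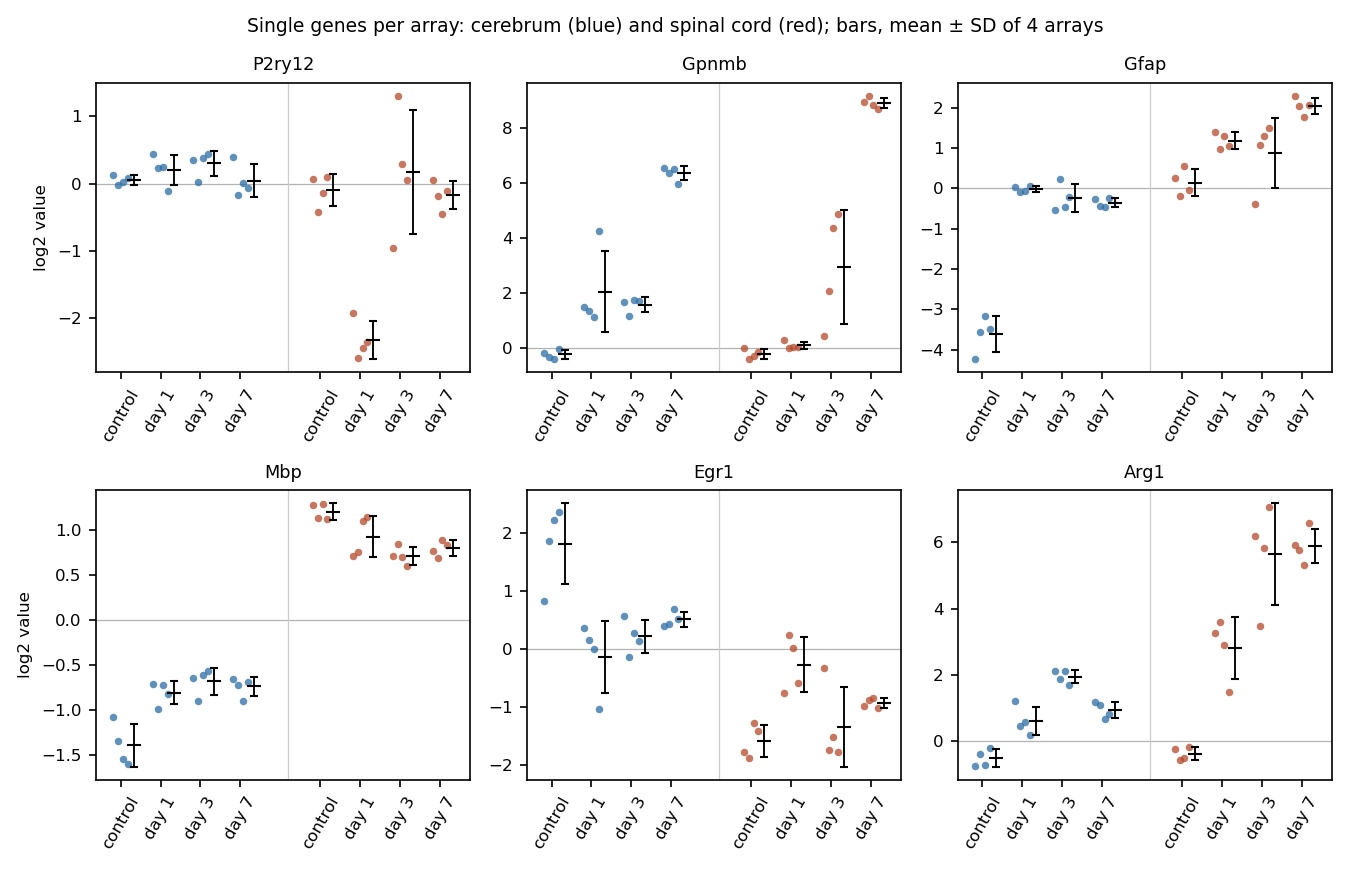
Log2 values of 6 genes on each of the 32 arrays (vertical axis), by tissue and time (horizontal axis), with the mean and SD of 4 arrays; day 3 and day 7 rest on rebuilt offsets. P2ry12 at spinal day 1 lies below spinal control by 4.69-fold, and Gpnmb rises to its highest values at day 7 in both tissues.

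Cerebral day 3 was compared with control to follow the brain response at its middle time. Lcn2 (26.1-fold, log2 4.70 ± 0.73), Mmp12 (20.4-fold, 4.35 ± 0.39) and Tgm1 (17.6-fold, 4.14 ± 0.44) rose most. Serpina3n, Plin2, Bcl2a1b, Gfap, Mpeg1, Pbk and Cdk1, the kinase of mitotic entry, followed from 3.91 to 3.16, and adjusted p over the 10 ran from 7.49e-14 to 0.000335. Prl (-2.75 ± 0.51), Nrgn (-1.84 ± 0.15) and Neurod6, a factor of cortical excitatory neurons (-1.53 ± 0.26), were among the largest falls, beside Fam189a1, Dtx3, Krt20, Pomc, Olfr1170, Olfr731 and Olfr1110 at -1.84 to -1.43. With cerebral controls 1 and 2 only, chosen after seeing the data, Prl stood at -1.62 (adjusted p = 0.0987, with 2.75e-05 to 0.0987 over its alternatives) Pomc at -0.824 and Neurod6 at -1.08 (0.0507, with 1.94e-05 to 0.0507). With controls 3 and 4 only, Prl stood at -3.89 and Pomc at -2.13. Pbk ran from 1.58 with the values as deposited to 4.60 with quantile normalisation on top, Cdk1 from 1.90 to 4.74, Mmp12 from 4.04 to 6.31, Tgm1 from 3.30 to 5.23 and Mpeg1 from 2.21 to 4.53, and Gfap stood at 2.54 under the latter.

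Complement had 6 higher, 0 lower and 5 not passed and kept its call with an estimated correlation (mean log2 change 1.17, adjusted p = 1.86e-09, and adjusted p = 0.0393 with an estimated correlation). Reactive astrocytes had 10 higher, 0 lower and 5 not passed (mean log2 change 1.63, adjusted p = 7.41e-13, and adjusted p = 0.0521 with an estimated correlation). Cell cycle had 14 higher, 0 lower and 3 not passed (mean log2 change 1.15, adjusted p = 1.78e-15, and adjusted p = 0.0619 with an estimated correlation). Activated microglia had 7 higher, 0 lower and 9 not passed (mean log2 change 1.06, adjusted p = 1.27e-11, and adjusted p = 0.0545 with an estimated correlation). Myelin genes had 2 higher, 0 lower and 15 not passed (mean log2 change 0.66, adjusted p = 2.9e-08, and adjusted p = 0.16 with an estimated correlation). Trf stood at 1.65 and Bcas1 at 1.01 past the test, while Mbp read 0.71 ± 0.11 and did not pass against its offset bound of 0.69. Thalamus genes had a mean log2 change of 0.78 beside them, with 6 of 14 higher and 0 lower. Neutrophil genes had 1 higher, 0 lower and 13 not passed (mean log2 change 0.048, adjusted p = 0.791), with a median below 0 against a mean and a test above 0. Complement had 7 higher and 0 lower adjusted over the list alone, reactive astrocytes 10 and 0, cell cycle 16 and 0, activated microglia 11 and 0, myelin 2 and 0 and neutrophils 1 and 0. In all, 1149 genes changed, 647 higher and 502 lower. The count was 2403 with quantile normalisation on top and 590 with controls 1 and 2 only, where myelin stood at 0.434. It was 3002 with the values as deposited, where cell cycle stood at 0.757, and 3888 with the offset taken as exact.

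Cerebral day 7 was compared with control to ask what marked the late phase of the brain injury. Mmp12 rose 197-fold (log2 7.62 ± 0.39), Gpnmb, a glycoprotein of lipid-laden phagocytes, 96.7-fold (6.59 ± 0.57), and Plin2 56.1-fold (5.81 ± 0.27). Lyz2, the lysozyme of myeloid cells, Lilrb4a, an inhibitory receptor of leukocytes, Mpeg1, Mir675, a microRNA from the H19 transcript, and the near-identical paralogs Bcl2a1a, Bcl2a1b and Bcl2a1d rose by 4.08 to 5.31. Adjusted p over the 10 ran from 9.01e-17 to 3.22e-07. Nr4a1 (-2.45 ± 0.25), Camkk2, a calcium-dependent kinase (-1.95 ± 0.15), Frzb, a Wnt antagonist (-1.72 ± 0.25), Arc, Nr4a2, Tbr1, Tafa1, Lamp5, Olfr731 and Olfr1170 fell, the last 7 at -1.53 to -1.29. With the values as deposited, Mmp12 stood at 4.80, Gpnmb at 3.61, Plin2 at 4.31, Lyz2 at 3.42, the other 6 rises from 2.34 for Mpeg1 to 4.34 for Bcl2a1b, and Lamp5 at -0.584, and Tbr1 stood at -2.30 and Nr4a1 at -3.37 with quantile normalisation on top. Olfr731 stood at -0.976 with cerebral controls 3 and 4 only (adjusted p = 0.0934, with 6.15e-05 to 0.0934 over its alternatives).

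Activated phagocytic microglia had 15 higher, 0 lower and 1 not passed, with the call kept under an estimated correlation (mean log2 change 2.34, adjusted p = 6.94e-26, and adjusted p = 0.00972 with an estimated correlation). The members included Tyrobp at 3.65, Igf1, a growth factor that acts on oligodendrocytes, at 3.34, and Trem2, a lipid-sensing receptor, at 2.68. Lipid uptake, storage and efflux had 7 higher, 0 lower and 4 not passed (mean log2 change 1.68, adjusted p = 7.81e-11, or 0.0292 with an estimated correlation). Cd36, a scavenger receptor, stood at 3.50 and Abca1, a cholesterol exporter, at 2.10. Complement had 7 higher, 0 lower and 4 not passed (mean log2 change 1.60, adjusted p = 1.22e-11, and adjusted p = 0.0295 with an estimated correlation). Type I interferon genes had 9 higher, 0 lower and 6 not passed (mean log2 change 1.07, adjusted p = 5.45e-10, and adjusted p = 0.0894 with an estimated correlation). MHC class II genes had 5 higher, 0 lower and 4 not passed (mean log2 change 0.84, adjusted p = 1.8e-05, and adjusted p = 0.0675 with an estimated correlation). Fibroblast and matrix genes had 7 higher, 0 lower and 8 not passed (mean log2 change 1.30, adjusted p = 3.05e-08, and adjusted p = 0.124 with an estimated correlation). Immediate early genes had 0 higher, 7 lower and 8 not passed (mean log2 change -0.90, adjusted p = 1.53e-06, and adjusted p = 0.0984 with an estimated correlation). Myelin genes had 1 higher, 0 lower and 16 not passed (mean log2 change 0.58, adjusted p = 3.08e-06, and adjusted p = 0.251 with an estimated correlation). Trf stood at 0.82 and Mbp at 0.65 ± 0.11, which did not pass, beside thalamus genes at 6 of 14 higher and 0 lower (mean log2 change 0.73). Activated microglia had 15 higher and 0 lower adjusted over the list alone, lipid handling 7 and 0, complement 7 and 0, interferon 11 and 0, MHC class II 6 and 0, matrix 8 and 0, immediate early genes 0 and 10 and myelin 2 and 0.

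In all, 1295 genes changed at cerebral day 7, 881 higher and 414 lower, and 389 of the higher and 61 of the lower changed at least 2-fold. The share higher was 68.0% and fell to 56.8% of 2132 genes with quantile normalisation on top. The count was 741 with controls 1 and 2 only, where myelin stood at 0.355, 2290 with the values as deposited and 4340 with the offset taken as exact. With the values as deposited, activated microglia stood at 1.5, lipid handling at 0.993, MHC class II at 0.418 and matrix at 0.732.

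Cerebral day 7 was also compared with cerebral day 1, which uses the controls only through the rebuilt offset. Genes of the activated microglia list rose further, with 9 higher, 0 lower and 7 not passed, 11 higher and 0 lower adjusted over the list alone (mean log2 change 1.22, adjusted p = 2.84e-13, and adjusted p = 0.0435 with an estimated correlation). Members that rose included Gpnmb at 4.31 ± 0.57, Cst7, a protease inhibitor, at 1.80 ± 0.28 and Lgals3, a galectin, at 1.79 ± 0.25. Lipid handling had 5 higher, 0 lower and 6 not passed, 6 higher and 0 lower adjusted over the list alone (mean log2 change 0.94, adjusted p = 5.22e-06, and adjusted p = 0.0698 with an estimated correlation). Cd36 stood at 2.90 and Fabp4 at 2.48. With the values as deposited, the 2 lists stood at 0.39 and 0.25, and the lipid call was lost (adjusted p = 0.087, with 5.63e-07 to 0.087 over its alternatives). Myelin genes had 0 higher, 0 lower and 17 not passed (mean log2 change 0.085, adjusted p = 0.848). Reactive astrocytes had 0 higher, 0 lower and 15 not passed (mean log2 change -0.26, adjusted p = 0.251). In all, 562 genes changed, 303 higher and 259 lower, and the count was 343 without cerebral day 1 replicate 2, 365 without cerebral day 1 replicate 3 and 316 without cerebral day 7 replicate 2. It was 1665 with quantile normalisation on top, 1052 in a fit of these groups only, 1143 with array weights, 365 with the values as deposited and 2962 with the offset taken as exact, and the share higher, 53.9%, was 37.0% with 75th percentile scaling.

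Spinal day 1 was compared with spinal control to ask what changed early after the cord injury. Tgm1 rose 45.2-fold (log2 5.50 ± 0.44), Lcn2 40.5-fold (5.34 ± 0.73), and Selp, the adhesion molecule P-selectin of activated endothelium and platelets, 26.8-fold (4.75 ± 0.69). Serpina3n, the matricellular gene Ccn1, Lilrb4a, the endothelial GTPase Rhoj, the matrix protein Tnc, the protease inhibitor Timp1 and Ms4a6d followed from 4.62 to 3.47, and adjusted p over the 10 ran from 3.35e-16 to 4.43e-06. P2ry12 fell 4.69-fold (-2.23 ± 0.25, adjusted p = 7.41e-08). Aspa, an enzyme of oligodendrocytes (-2.09 ± 0.36), Gng8, a G protein subunit (-2.50 ± 0.21), Depdc7, Car14, Hhip and Myorg fell too, the last 4 at -2.15 to -2.03. The muscle genes Myh8, Myh1 and Tnnt3 were lower, at -4.07, -2.49 and -2.09.

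Reactive astrocytes had 14 higher, 0 lower and 1 not passed, a call kept with an estimated correlation (mean log2 change 2.44, adjusted p = 8.18e-16, and adjusted p = 0.0363 with an estimated correlation). Hspb1 stood at 3.30 and Gfap at 1.05 ± 0.26. Inflammatory cytokines and chemokines had 16 higher, 0 lower and 3 not passed (mean log2 change 1.29, adjusted p = 9.11e-12, and adjusted p = 0.0393 with an estimated correlation). Ccl3 stood at 3.43 and Il1b at 2.84. Immediate early genes had 11 higher, 0 lower and 4 not passed (mean log2 change 1.17, adjusted p = 7.18e-07, and adjusted p = 0.0894 with an estimated correlation). Atf3 stood at 2.63. Homeostatic microglia had 2 higher, 4 lower and 6 not passed (mean log2 change -0.43, adjusted p = 0.135). Beside P2ry12, Siglech was lower at -1.81, Slc2a5 at -0.90 and Sall1 at -0.52, and Olfml3 rose by 0.85 and Tmem119 by 0.43. Activated microglia had 8 higher, 0 lower and 8 not passed (mean log2 change 0.49, adjusted p = 0.00242, and adjusted p = 0.36 with an estimated correlation). Neutrophils had 8 higher, 0 lower and 6 not passed (mean log2 change 0.73, adjusted p = 0.00334, and adjusted p = 0.374 with an estimated correlation). Reactive astrocytes had 15 higher and 0 lower adjusted over the list alone, cytokines 19 and 0, immediate early genes 11 and 0, homeostatic microglia 2 and 6, activated microglia 8 and 0 and neutrophils 8 and 0.

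Myelin genes at spinal day 1 had 2 higher, 10 lower and 5 not passed, 2 higher and 11 lower adjusted over the list alone (mean log2 change -0.64, adjusted p = 0.0013, and adjusted p = 0.414 with an estimated correlation). Ugt8a was lower at -1.80, Fa2h at -1.55 and Mog at -1.28, Trf rose by 1.05 and Myrf by 0.51, and Mbp read -0.28 ± 0.11, not passed. Oligodendrocyte precursors had 0 higher, 5 lower and 8 not passed, 0 higher and 5 lower adjusted over the list alone (mean log2 change -0.48, adjusted p = 0.0148, and adjusted p = 0.509 with an estimated correlation). Gpr17, a receptor of cells about to differentiate, stood at -1.63. All 12 skeletal muscle genes were lower, also adjusted over the list alone (mean log2 change -1.88, adjusted p = 9.87e-07, and adjusted p = 0.251 with an estimated correlation), against control scores that ran from 0.236 to 3.62. In all, 6224 genes changed, 3083 higher and 3141 lower. With spinal controls 3 and 4 only, chosen after seeing the data, the muscle list stood at -0.573, Myh8 at -1.77, Myh1 at -0.788 and Tnnt3 at -0.582 (adjusted p = 0.0994, with 3.05e-06 to 0.0994 over its alternatives).

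Spinal day 3 was compared with control to follow the cord response at its middle time. Arg1, an arginine-degrading enzyme of macrophages, rose 64.6-fold (log2 6.01 ± 0.44), Tgm1 62.1-fold (5.96 ± 0.44) and Lcn2 37.4-fold (5.22 ± 0.73). Selp, Lilrb4a, Pbk, Ms4a6d, Prg4, a lubricating proteoglycan, Tagln, an actin-binding protein of smooth muscle, and Mki67 rose by 4.93 to 4.33, and adjusted p over the 10 ran from 1.69e-13 to 0.00149. With quantile normalisation on top, Tgm1 stood at 4.90, Lcn2 at 4.37 and the last 7 at 3.23 to 3.98, and Arg1 at 5.26 with the values as deposited. Hrh3, a histamine receptor (-2.21 ± 0.15), Tac2, a tachykinin (-2.14 ± 0.32), Fa2h, which hydroxylates myelin lipids (-1.99 ± 0.27), and Grm3, a glutamate receptor (-1.92 ± 0.28), fell, beside Gng8, Car14 and Hhip at -2.31 to -1.83. The muscle-expressed genes Myot, Cox8b and Mb were lower at -1.83, -1.80 and -1.76.

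All 17 cell cycle genes rose, also adjusted over the list alone (mean log2 change 1.82, adjusted p = 3.44e-18, or 0.0494 with an estimated correlation). Monocytes and macrophages had 13 higher, 0 lower and 2 not passed (mean log2 change 2.25, adjusted p = 5.64e-13, or 0.0398 with an estimated correlation). Reactive astrocytes had 13 higher, 0 lower and 2 not passed (mean log2 change 2.44, adjusted p = 1.23e-14, or 0.0393 with an estimated correlation). Complement had 8 higher, 0 lower and 3 not passed (mean log2 change 1.68, adjusted p = 1.69e-10, and adjusted p = 0.0363 with an estimated correlation), and these 4 lists kept their calls with an estimated correlation. Homeostatic microglia had 5 higher, 0 lower and 7 not passed (mean log2 change 0.54, adjusted p = 0.0153, and adjusted p = 0.531 with an estimated correlation). P2ry12 stood at 0.27 ± 0.25, not passed. The list stood at 0.337 without spinal day 3 replicate 2 (adjusted p = 0.185, with 2.14e-07 to 0.531 over its alternatives) and at 0.96 without replicate 1. Myelin had 1 higher, 3 lower and 13 not passed (mean log2 change -0.56, adjusted p = 0.00478, and adjusted p = 0.487 with an estimated correlation). Opalin was lower at -0.93, and Mbp read -0.49 ± 0.11, not passed, and the list stood at -0.99 with quantile normalisation on top. Neurons had 0 higher, 8 lower and 8 not passed (mean log2 change -0.61, adjusted p = 0.000142, and adjusted p = 0.244 with an estimated correlation). Monocytes had 14 higher and 0 lower adjusted over the list alone, reactive astrocytes 14 and 0, complement 9 and 0, homeostatic microglia 5 and 0, myelin 1 and 3 and neurons 0 and 11.

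Muscle genes at spinal day 3 had 0 higher, 11 lower and 1 not passed, 0 higher and 12 lower adjusted over the list alone (mean log2 change -1.70, adjusted p = 5.19e-05, and adjusted p = 0.333 with an estimated correlation). With spinal controls 3 and 4 only, the list stood at -0.399 (adjusted p = 0.176, with 1.13e-09 to 0.333 over its alternatives) Myot at -0.802, Mb at -0.736 and Cox8b at -0.671 (0.304, with 2.72e-05 to 0.304). In all, 3742 genes changed, 1953 higher and 1789 lower, a share higher of 52.2% that was 64.2% with median scaling. The count was 2251 with quantile normalisation on top, 2010 in a fit of these groups only, where the calls of Mb (adjusted p = 0.0518, with 2.39e-07 to 0.0518 over its alternatives) and Myot (0.059, with 1.29e-06 to 0.059) also ended, 6250 with the values as deposited, where Pbk stood at 3.18, and 7470 with the offset taken as exact.

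Spinal day 7 was compared with control to ask what marked the late phase of the cord injury. Mmp12 rose 664-fold (log2 9.38 ± 0.39), Gpnmb 560-fold (9.13 ± 0.57) and Cd36 172-fold (7.42 ± 0.28). Lilrb4a, Lgals3, Ms4a7, a membrane protein of macrophages, Lyz2, Mir675, Plin2 and Arg1 rose by 6.69 to 6.26, and adjusted p over the 10 ran from 1.02e-18 to 2.6e-10. With quantile normalisation on top, Mmp12 stood at 6.59, Gpnmb at 6.70, Cd36 at 4.98, the other 7 rises from 3.99 for Mir675 to 4.50 for Lilrb4a, Nrn1 at -2.50, Scn1a at -1.86, Elmod1 at -1.83 and Hdgfl3 at -1.71. Nrn1, a neurite growth factor (-3.46 ± 0.29), Tac2 (-2.84 ± 0.32), Insig1, a regulator of sterol synthesis (-2.70 ± 0.20), and Scn1a, a neuronal sodium channel (-2.62 ± 0.20), fell, beside Lypd6b, Elmod1, Sgpp2 and Hdgfl3 at -3.28 to -2.58. The muscle genes Myh4 and Myh8 were lower at -4.99 and -3.71, or -2.31 and -1.41 with spinal controls 3 and 4 only. Insig1 and Sgpp2 stood at -1.62 and -1.66 with the values as deposited, Mmp12 at 6.56, Gpnmb at 6.14 and Mir675 at 3.7.

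Activated phagocytic microglia had 15 higher, 0 lower and 1 not passed (mean log2 change 3.36, adjusted p = 8.18e-16, or 0.0363 with an estimated correlation). Complement had 10 higher, 0 lower and 1 not passed (mean log2 change 2.85, adjusted p = 1.18e-10, or 0.0363 with an estimated correlation). Lipid handling had 10 higher, 0 lower and 1 not passed (mean log2 change 3.06, adjusted p = 4.92e-11, or 0.0292 with an estimated correlation). Trem2 rose by 5.08, Tyrobp by 5.06, Abca1 by 5.13 and C3ar1 by 5.94. All 16 neuronal genes fell (mean log2 change -1.40, adjusted p = 4.1e-09, and adjusted p = 0.0675 with an estimated correlation). Rbfox3 stood at -2.0. Cholesterol synthesis had 0 higher, 11 lower and 2 not passed (mean log2 change -1.40, adjusted p = 1.5e-08, and adjusted p = 0.0675 with an estimated correlation). Hmgcs1, the enzyme that makes HMG-CoA, stood at -1.80 and Msmo1 at -2.02. Fibroblast and matrix genes had 14 higher, 0 lower and 1 not passed (mean log2 change 3.30, adjusted p = 5.86e-13, and adjusted p = 0.0556 with an estimated correlation). Postn stood at 5.83 and Col3a1 at 4.92, and all 17 cell cycle genes rose (mean log2 change 2.51, adjusted p = 1.35e-15, and adjusted p = 0.0619 with an estimated correlation). Neutrophils had 10 higher, 0 lower and 4 not passed (mean log2 change 1.96, adjusted p = 2.16e-06, and adjusted p = 0.158 with an estimated correlation). Ngp, a granule protein of immature neutrophils, stood at 4.24. Under quantile normalisation, activated microglia stood at 2.01, complement at 1.76, lipid handling at 1.75, neurons at -0.839, matrix at 1.84, cell cycle at 1.47 and neutrophils at 0.936. Activated microglia had 15 higher and 0 lower adjusted over the list alone, complement 11 and 0, lipid handling 11 and 0, neurons 0 and 16, cholesterol synthesis 0 and 11, matrix 15 and 0, cell cycle 17 and 0 and neutrophils 10 and 0.

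Myelin genes at spinal day 7 had 0 higher, 4 lower and 13 not passed (mean log2 change -0.63, adjusted p = 0.0183, and adjusted p = 0.573 with an estimated correlation). Opalin was lower at -2.02, Ugt8a at -1.27, Mal at -1.09 and Tspan2 at -0.76, and Mbp read -0.41 ± 0.11, not passed. Oligodendrocyte precursors had 2 higher, 2 lower and 9 not passed (mean log2 change 0.20, adjusted p = 0.588). Gpr17 rose by 1.38 and Cspg4 by 2.05, and Olig2 was lower at -0.64 and C1ql1 at -0.54. Growth factors acting on oligodendroglia had 6 higher, 1 lower and 7 not passed (mean log2 change 1.04, adjusted p = 0.00734, and adjusted p = 0.135 with an estimated correlation). Igf1 stood at 4.13. Lymphocytes had 1 higher, 0 lower and 15 not passed (mean log2 change 0.30, adjusted p = 0.313), the rise being in Il7r at 4.05. The hypoxia response had 7 higher, 2 lower and 6 not passed (mean log2 change 0.62, adjusted p = 0.0931). Muscle genes had 0 higher, 9 lower and 3 not passed (mean log2 change -1.75, adjusted p = 0.00282, and adjusted p = 0.488 with an estimated correlation). With spinal controls 3 and 4 only, they stood at -0.45 (adjusted p = 0.514, with 3.15e-06 to 0.514 over its alternatives). Myelin had 0 higher and 4 lower adjusted over the list alone, precursors 2 and 2, growth factors 6 and 1, lymphocytes 1 and 0, hypoxia 8 and 4 and muscle 0 and 9. In all, 6207 genes changed, 2975 higher and 3232 lower, and the count was 3464 with quantile normalisation on top and 9754 with the offset taken as exact. Quantile normalisation also left myelin at -1.15 and growth factors at 0.588.

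Spinal day 7 was also compared with spinal day 1. P2ry12 rose by 2.16 ± 0.25 and Siglech by 1.11 ± 0.30, within a homeostatic microglia list at 9 higher, 0 lower and 3 not passed (mean log2 change 1.55, adjusted p = 3.54e-06, and adjusted p = 0.243 with an estimated correlation). Activated microglia had 14 higher, 0 lower and 2 not passed (mean log2 change 2.87, adjusted p = 2.91e-15, and adjusted p = 0.0363 with an estimated correlation). Gpnmb rose by 8.82 ± 0.57 and Trem2 by 5.65 ± 0.33. Lipid handling had 10 higher, 0 lower and 1 not passed (mean log2 change 2.96, adjusted p = 4.04e-13, and adjusted p = 0.0161 with an estimated correlation), led by Cd36 at 7.60 ± 0.28. Oligodendrocyte precursors had 4 higher, 0 lower and 9 not passed (mean log2 change 0.68, adjusted p = 0.0175, and adjusted p = 0.518 with an estimated correlation). Gpr17 stood at 3.01 ± 0.37 and Cspg4 at 2.43 ± 0.19. Myelin had 2 higher, 3 lower and 12 not passed (mean log2 change 0.0069, adjusted p = 0.878). Cnp rose by 0.82 and Enpp6, expressed as oligodendrocytes start to myelinate, by 1.67, and Myrf was lower at -0.66. The mean of the myelin list lay above 0 while its median and its test lay below. Inflammatory cytokines had 2 higher, 8 lower and 9 not passed (mean log2 change -0.45, adjusted p = 0.214). Neurons had 0 higher, 14 lower and 2 not passed (mean log2 change -1.04, adjusted p = 1.45e-07, and adjusted p = 0.0963 with an estimated correlation). With quantile normalisation on top, homeostatic microglia stood at 1.0, activated microglia at 1.49, lipid handling at 1.69 and neurons at -0.583. Homeostatic microglia had 9 higher and 0 lower adjusted over the list alone, activated microglia 14 and 0, lipid handling 11 and 0, precursors 4 and 0, myelin 2 and 3, cytokines 3 and 10 and neurons 0 and 15. In all, 5391 genes changed, 2712 higher and 2679 lower, a share higher of 50.3% that was 61.6% of 1985 with quantile normalisation on top and 65.8% with median scaling. The median of all genes lay at -0.126 in this comparison, and the count was 9661 with the offset taken as exact.

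**Figure D3:**
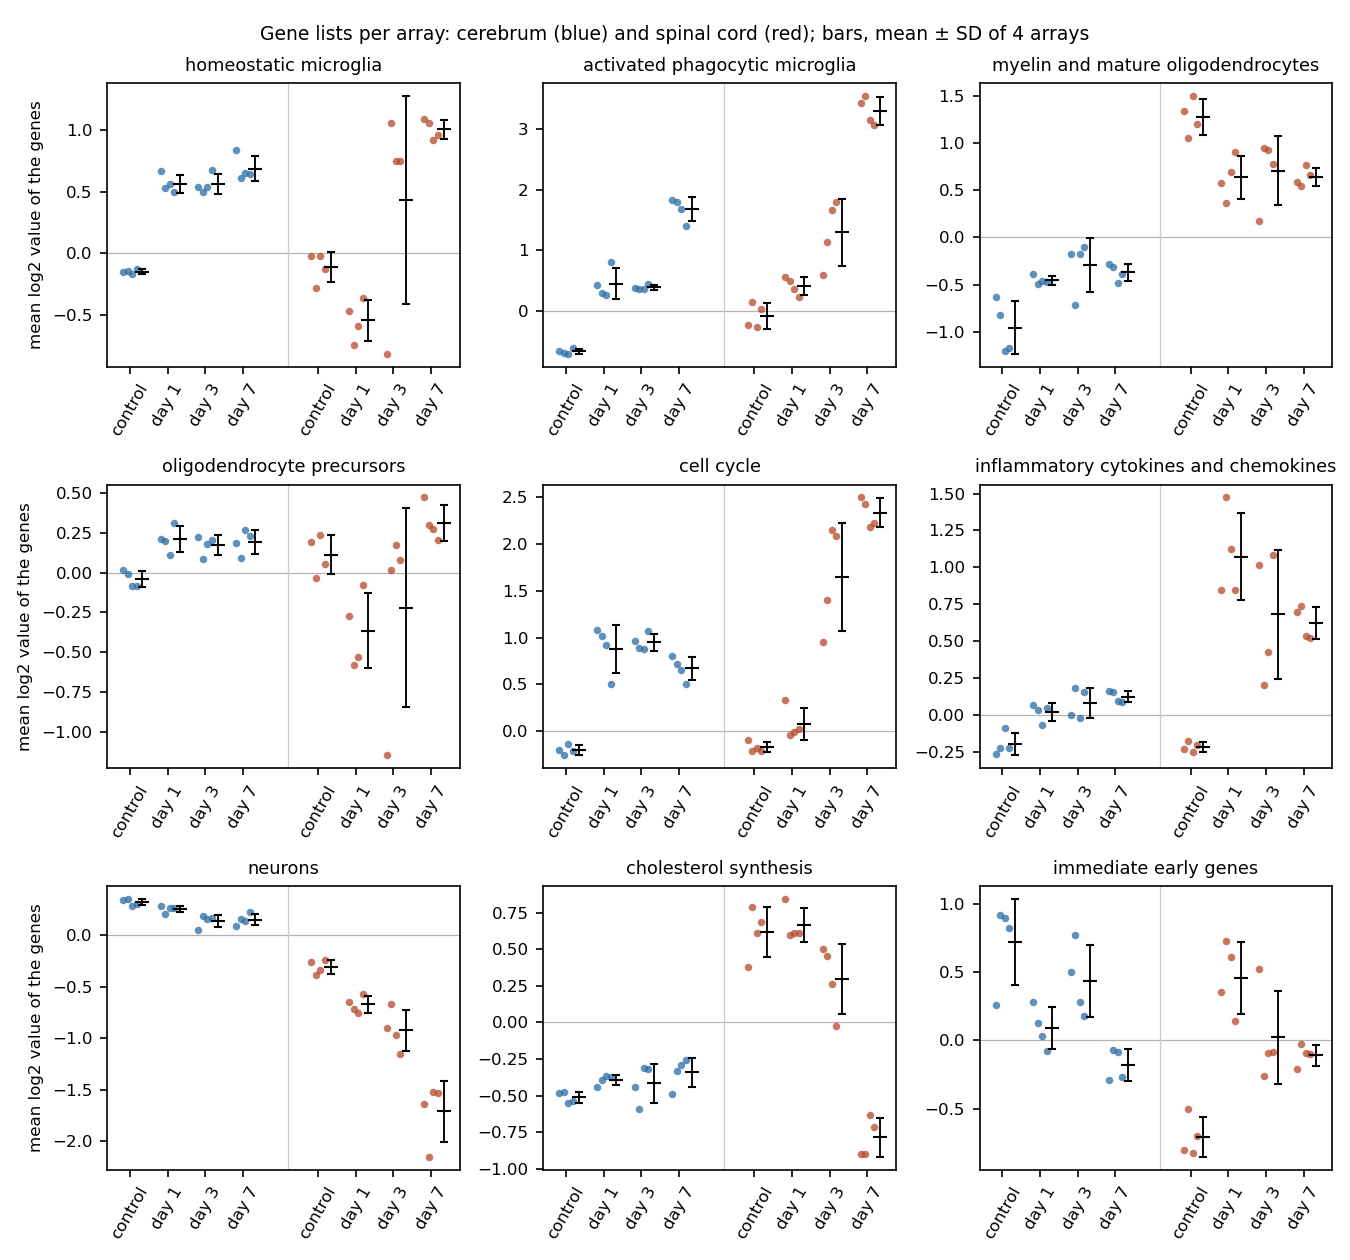
Mean log2 value of the genes of 9 lists on each array (vertical axis), by tissue and time (horizontal axis), with the mean and SD of 4 arrays; day 3 and day 7 rest on rebuilt offsets. Against control, myelin genes stand at 0.50, 0.66 and 0.58 in the cerebrum and at -0.64, -0.56 and -0.63 in the cord at days 1, 3 and 7.

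The series asks how the cerebral and the spinal injury differ, so the spinal response was tested against the cerebral response at each day, as the spinal change minus the cerebral change. At day 1, Prg4 (4.17 ± 1.22), Ccn1 (3.64 ± 0.50), Junb (3.52 ± 0.32), Egr2 (3.44 ± 0.61) and Egr1 (3.26 ± 0.42) had the largest positive differences. Egr1 changed by 1.32 in the cord and -1.94 in the cerebrum, and Egr2 by 1.67 and -1.77. Mpeg1 (-3.69 ± 0.40) and Mmp12 (-3.24 ± 0.55) had negative differences, Mmp12 with 2.36 in the cord and 5.60 in the cerebrum, and stood at -4.92 with quantile normalisation on top. The muscle genes Atp2a1, Myh4 and Myh8 stood at -4.62, -4.61 and -4.21, and over the 10 genes adjusted p ran from 7.11e-08 to 0.0238.

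Homeostatic microglia differed at day 1, with 0 higher, 6 lower and 6 not passed (mean log2 change -1.14, adjusted p = 1.37e-06, and adjusted p = 0.218 with an estimated correlation). P2ry12 stood at -2.38 ± 0.35 and Siglech at -2.41 ± 0.42. Myelin had 0 higher, 12 lower and 5 not passed (mean log2 change -1.14, adjusted p = 2.83e-12, and adjusted p = 0.0819 with an estimated correlation). Aspa stood at -2.43 and Mbp at -0.86 ± 0.16. Oligodendrocyte precursors had 0 higher, 4 lower and 9 not passed (mean log2 change -0.73, adjusted p = 0.000295, and adjusted p = 0.312 with an estimated correlation). Immediate early genes had 10 higher, 0 lower and 5 not passed, the call that held with an estimated correlation (mean log2 change 1.80, adjusted p = 1.72e-15, and adjusted p = 0.0238 with an estimated correlation). Cytokines had 10 higher, 0 lower and 9 not passed (mean log2 change 1.07, adjusted p = 1.39e-08, and adjusted p = 0.0675 with an estimated correlation). Cell cycle had 0 higher, 7 lower and 10 not passed (mean log2 change -0.83, adjusted p = 6.31e-06, and adjusted p = 0.261 with an estimated correlation). Mki67 stood at -3.15 ± 0.51, and the list at -1.33 with quantile normalisation on top. Reactive astrocytes had 8 higher, 1 lower and 6 not passed (mean log2 change 0.98, adjusted p = 8.41e-05, and adjusted p = 0.256 with an estimated correlation). Timp1 stood at 3.15 against Gfap at -2.55 ± 0.36. Homeostatic microglia had 0 higher and 6 lower adjusted over the list alone, myelin 0 and 14, precursors 0 and 8, immediate early genes 15 and 0, cytokines 13 and 0, cell cycle 0 and 10 and reactive astrocytes 8 and 1. The tissue markers moved with these groups, since thalamus genes were higher in the injured cerebrum (mean 0.83) and muscle genes lower in the injured cord (mean -1.88).

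In all, 2200 genes responded differently at day 1, 917 with a positive and 1283 with a negative difference, a share positive of 41.7% that was 28.1% with 75th percentile scaling, which moved the group medians by -0.143 to -0.24. The count was 1056 with cerebral controls 1 and 2 only. Prg4 lost its call without spinal control replicate 1 (3.66, adjusted p = 0.0527) or 3 (3.44, 0.0652) and without spinal day 1 replicate 2 (3.70, 0.0602) or 3 (3.85, 0.0535), against 0.0012 to 0.0758 over its alternatives. With spinal controls 3 and 4 only, Atp2a1 stood at -2.44 (0.063, with 9.27e-05 to 0.063), Myh4 at -1.94 (0.17, with 0.00011 to 0.17) and Myh8 at -1.92 (0.063, with 0.000125 to 0.063).

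At day 3, Arg1 had the largest positive difference (3.56 ± 0.62), with 6.01 in the cord and 2.46 in the cerebrum. The acute phase genes Saa3 (3.47 ± 0.73) and Lbp (3.05 ± 0.80), Chil3, a chitinase-like protein of macrophages (3.23 ± 0.76), and Tagln (3.01 ± 0.37) followed. Glra1 (-3.93 ± 0.39) and Ebf3 (-3.17 ± 0.40), both high in spinal controls, stood at -1.55 and -1.05 in the cord and at 2.38 and 2.12 in the cerebrum, and none of these 4 changes passed the test by itself. Adjusted p over the 10 genes, which include Atp2a1, Myh4 and Myh8 at -4.19, -3.90 and -3.63, ran from 6.1e-07 to 0.0429.

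Myelin had 0 higher, 14 lower and 3 not passed (mean log2 change -1.23, adjusted p = 8.18e-16, and adjusted p = 0.0521 with an estimated correlation). Fa2h stood at -1.97 and Mbp at -1.20 ± 0.16, beside thalamus genes higher in the injured cerebrum (mean 0.78). Homeostatic astrocytes had 0 higher, 6 lower and 5 not passed (mean log2 change -0.91, adjusted p = 1.25e-06, or 0.156 with an estimated correlation). Monocytes and macrophages had 9 higher, 0 lower and 6 not passed (mean log2 change 1.36, adjusted p = 4.1e-09, or 0.0707 with an estimated correlation). Immediate early genes had 8 higher, 0 lower and 7 not passed (mean log2 change 1.02, adjusted p = 7.58e-08, or 0.0685 with an estimated correlation). Homeostatic microglia had 0 higher, 0 lower and 12 not passed (mean log2 change -0.17, adjusted p = 0.646) and P2ry12 stood at 0.026 ± 0.35. Oligodendrocyte precursors had 0 higher, 3 lower and 10 not passed (mean log2 change -0.55, adjusted p = 0.00112, and adjusted p = 0.371 with an estimated correlation). Without spinal day 3 replicate 1, the list stood at -0.236 (adjusted p = 0.0702, with 6.98e-05 to 0.371 over its alternatives). Cell cycle had 5 higher, 0 lower and 12 not passed (mean log2 change 0.67, adjusted p = 1.37e-06, or 0.251 with an estimated correlation). Complement had 3 higher, 0 lower and 8 not passed (mean log2 change 0.52, adjusted p = 0.00478, or 0.266 with an estimated correlation). With quantile normalisation on top, monocytes stood at 0.55, and cell cycle and complement stood at -0.278 (adjusted p = 0.233, with 5.33e-13 to 0.251 over its alternatives) and -0.12 (0.774, with 0.000101 to 0.774). Myelin had 0 higher and 16 lower adjusted over the list alone, homeostatic astrocytes 0 and 8, monocytes 10 and 0, immediate early genes 9 and 0, homeostatic microglia 0 and 0, precursors 0 and 3, cell cycle 9 and 0 and complement 3 and 0.

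In all, 1808 genes responded differently at day 3, 796 with a positive and 1012 with a negative difference, a share positive of 44.0% that was 30.6% with 75th percentile scaling. The count was 955 in a fit of these groups only, where Chil3 lost its call (adjusted p = 0.062, with 3.08e-05 to 0.062 over its alternatives), 828 with the allowance as a bound and 873 with cerebral controls 1 and 2 only. Arg1 stood at 1.90 with quantile normalisation on top (adjusted p = 0.0652, with 5.85e-07 to 0.0652 over its alternatives) Tagln at 1.5 under the same setting, and Lbp at 2.76 with cerebral controls 3 and 4 only (0.0585, with 0.00177 to 0.0585). Myh4 lost its call without any 1 of the 4 cerebral controls or the 4 cerebral day 3 arrays (-3.97 to -3.85), without spinal control replicate 1 (-3.06) or 2 (-2.96) and without spinal day 3 replicate 2 (-3.75), 3 (-3.60) or 4 (-3.41), against adjusted p of 0.000495 to 0.451 over its alternatives. Myh8 lost its call without spinal control replicate 1 (-2.79, 0.0583). With spinal controls 3 and 4 only, Atp2a1 stood at -2.02 (0.143, with 0.000264 to 0.143), Myh4 at -1.23 and Myh8 at -1.34.

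At day 7, Arg1 again had the largest positive difference (4.82 ± 0.62), with 6.26 in the cord and 1.44 in the cerebrum, where it did not pass. Ngp (4.50 ± 0.49), Anpep, a membrane peptidase (4.05 ± 0.53), Cd36 (3.92 ± 0.40) and Col5a1, a fibrillar collagen (3.85 ± 0.39), followed. Tac2 (-3.23 ± 0.46), Glra1 (-3.40 ± 0.39) and Ebf3 (-3.40 ± 0.40) had negative differences, with Glra1 and Ebf3 at 2.35 and 2.19 in the cerebrum, not passed. Adjusted p over the 10 genes, which include Myh4 and Atp2a1 at -4.83 and -4.37, ran from 2.46e-08 to 0.00349.

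All 13 cholesterol synthesis genes fell more or rose less in the cord at day 7 (mean log2 change -1.57, adjusted p = 1.81e-14, and adjusted p = 0.0295 with an estimated correlation). Insig1 stood at -2.56 ± 0.28 and Hmgcs1 at -2.41 ± 0.23, the list whose call held with an estimated correlation. Myelin had 0 higher, 13 lower and 4 not passed (mean log2 change -1.21, adjusted p = 2.52e-08, or 0.158 with an estimated correlation). Mbp stood at -1.06 ± 0.16 and Ermn at -2.18, beside thalamus genes higher in the injured cerebrum (mean 0.73). Neurons had 0 higher, 15 lower and 1 not passed (mean log2 change -1.23, adjusted p = 1.27e-10, or 0.0521 with an estimated correlation). Monocytes and macrophages had 9 higher, 0 lower and 6 not passed (mean log2 change 1.76, adjusted p = 4.7e-07, or 0.118 with an estimated correlation). Neutrophils had 8 higher, 0 lower and 6 not passed (mean log2 change 1.74, adjusted p = 3.11e-06, or 0.161 with an estimated correlation). Fibroblasts and matrix had 12 higher, 1 lower and 2 not passed (mean log2 change 2.0, adjusted p = 3.22e-09, or 0.0999 with an estimated correlation), where Sparc, a matrix protein, was the lower gene at -0.89. Type I interferon genes had 0 higher, 5 lower and 10 not passed (mean log2 change -0.49, adjusted p = 0.0719). Activated microglia had 9 higher, 1 lower and 6 not passed (mean log2 change 1.03, adjusted p = 9.71e-05, or 0.251 with an estimated correlation). Lgals3 stood at 3.41 ± 0.35 and Trem2 at 2.40 ± 0.47 against Csf1 at -0.52. Lipid handling had 6 higher, 0 lower and 5 not passed (mean log2 change 1.38, adjusted p = 1.25e-06, and adjusted p = 0.0619 with an estimated correlation). Quantile normalisation on top turned the activated microglia shift to -0.515 (adjusted p = 0.00306, with 3.12e-06 to 0.251 over its alternatives) and the lipid shift to -0.179 (0.686, with 1.54e-07 to 0.686). It left neurons at -0.469, neutrophils at 0.688, monocytes at 0.495 (0.0583, with 5.22e-10 to 0.118) and matrix at 0.367 (0.0809, with 9.21e-12 to 0.0999). Cholesterol synthesis had 0 higher and 13 lower adjusted over the list alone, myelin 0 and 14, neurons 0 and 16, monocytes 11 and 0, neutrophils 8 and 0, matrix 13 and 1, interferon 0 and 5, activated microglia 10 and 1 and lipid handling 10 and 0.

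In all, 5382 genes responded differently at day 7, 2541 with a positive and 2841 with a negative difference. The count was 3239 with quantile normalisation on top, where Cd36 stood at 0.832 (adjusted p = 0.205, with 4.09e-09 to 0.205 over its alternatives) Arg1 at 2.32, Ngp at 2.38, Col5a1 at 2.02 and Anpep at 1.46 (0.0587, with 2.31e-08 to 0.0587), and 3564 with the allowance as a bound. With spinal controls 3 and 4 only, Myh4 stood at -2.16 (0.0774, with 6.45e-06 to 0.0774) and Atp2a1 at -2.19 (0.0563, with 1.44e-05 to 0.0563).

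**Figure D4:**
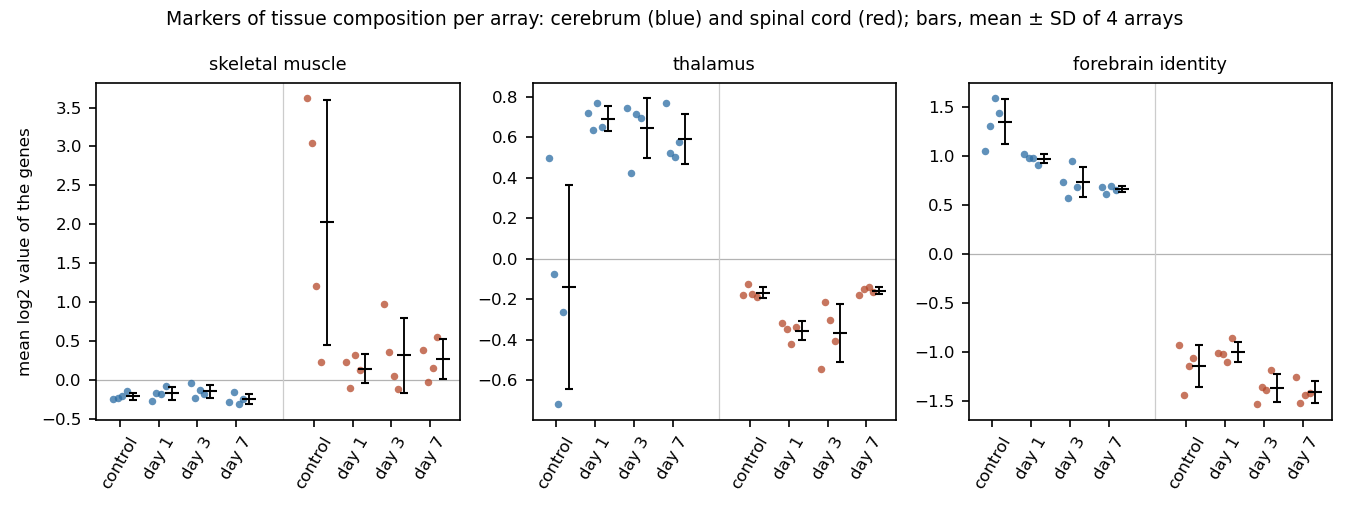
Mean log2 value of the skeletal muscle, thalamus and forebrain identity genes on each array (vertical axis), by tissue and time. Muscle scores of the spinal controls run from 0.236 to 3.62 and those of the injured spinal arrays from -0.113 to 0.98.

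The cerebral and the spinal changes were then set side by side to ask how far the responses are shared. Across genes, which are not independent replicates, the changes had a Pearson r of 0.411 at day 1, 0.625 at day 3 and 0.667 at day 7, and a Spearman rho of 0.361, 0.522 and 0.469. In data simulated with no effect, the rebuilt offsets shared by the tissues gave an r of 0.143 at day 3 and 0.142 at day 7, and covariances of 0.0044 and 0.00421 against the measured 0.128 and 0.227. Genes higher in both tissues numbered 735, 486 and 737 against 275, 64.8 and 134 expected from the single counts, and genes lower in both 695, 251 and 271 against 258, 46 and 68.6. Genes called in opposite directions numbered 146, 3 and 20. Calls at days 3 and 7 faced an offset bound, so these counts are not comparable with day 1. The SD of the spinal changes was 1.32, 1.48 and 1.92 times that of the cerebral changes.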

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

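The tests chosen only after the result was seen are those with cerebral controls 1 and 2 only, the spread of the muscle score, the controls within the range of the injured arrays, the spread of the microglia changes and P2ry12 over the scalings.

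In 16 of 232 groups of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20 groups, or 11.6. Spinal day 3 replicate 1 stood at -0.816 in homeostatic microglia (others 0.744 to 1.05) and -1.15 in oligodendrocyte precursors (0.0154 to 0.173). Cerebral day 3 replicate 2 stood at -0.712 in myelin (-0.172 to -0.102) and -0.0813 in MHC class II (0.213 to 0.233), with a mean correlation with its group of 0.511 (0.636 to 0.658). Matrix genes stood at 2.13 in spinal day 3 replicate 3 (1.4 to 1.52) and 0.558 in cerebral day 7 replicate 4 (0.809 to 0.858). Spinal day 1 replicate 1 stood at 0.338 in cell cycle (-0.0397 to 0.0204) and 0.845 in cholesterol synthesis (0.601 to 0.613). Cerebral control replicate 1 stood at -0.594 in hypoxia (-0.398 to -0.377), 0.256 in immediate early genes (0.821 to 0.918) and -0.227 in growth factors (-0.0893 to -0.0695). Hypoxia stood at 0.0418 in cerebral day 1 replicate 1 (-0.126 to -0.112) and 0.439 in spinal day 7 replicate 3 (0.635 to 0.64), and growth factors at 0.936 in spinal day 7 replicate 1 (1.07 to 1.1). Spinal control replicate 2 had an SD over genes of 0.502 (0.41 to 0.411).

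The spinal and the cerebral response differed, by a test of the difference itself, in 2200 genes at day 1, 1808 at day 3 and 5382 at day 7. At day 1, the mean differences of called lists, of which only immediate early genes kept the call with an estimated correlation, were -1.14 for homeostatic microglia, -0.623 for activated microglia, 0.653 for neutrophils, -0.729 for oligodendrocyte precursors, -1.14 for myelin, -0.767 for homeostatic astrocytes, 0.983 for reactive astrocytes and -0.295 for neurons. They were -0.335 for endothelial cells, -0.83 for cell cycle, 1.07 for cytokines, 1.8 for immediate early genes, -0.644 for lipid handling, -1.91 for skeletal muscle, 0.518 for forebrain identity and -0.464 for Hox genes. Quantile normalisation on top ended the calls of neurons (-0.0907) and Hox genes (-0.0862). The genes were Prg4 at 4.17, Ccn1 at 3.64, Junb at 3.52, Egr2 at 3.44, Egr1 at 3.26, Atp2a1 at -4.62, Myh4 at -4.61, Myh8 at -4.21, Mpeg1 at -3.69 and Mmp12 at -3.24.

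At day 3, the lists, of which none kept the call with an estimated correlation, were monocytes at 1.36, neutrophils at 0.708, oligodendrocyte precursors at -0.546, myelin at -1.23, homeostatic astrocytes at -0.909, reactive astrocytes at 0.801, neurons at -0.43, endothelial cells at 0.26 and matrix at 0.925. Cell cycle stood at 0.67, cytokines at 0.618, complement at 0.516, immediate early genes at 1.02, cholesterol synthesis at -0.412, skeletal muscle at -1.77, forebrain identity at 0.39 and Hox genes at -0.336. Quantile normalisation on top ended the calls of reactive astrocytes (0.223), neurons (-0.123), endothelial cells (0.0163) and matrix (0.396), and turned cell cycle to -0.278 and complement to -0.12. The genes were Arg1 at 3.56, Saa3 at 3.47, Chil3 at 3.23, Lbp at 3.05, Tagln at 3.01, Atp2a1 at -4.19, Glra1 at -3.93, Myh4 at -3.90, Myh8 at -3.63 and Ebf3 at -3.17.

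At day 7, the lists, of which only cholesterol synthesis kept the call with an estimated correlation, were activated microglia at 1.03, monocytes at 1.76, neutrophils at 1.74, myelin at -1.21, reactive astrocytes at 0.863, neurons at -1.23, matrix at 2.0 and cell cycle at 1.64. Cytokines stood at 0.514, complement at 1.25, MHC class II at 0.532, immediate early genes at 1.5, cholesterol synthesis at -1.57, lipid handling at 1.38, skeletal muscle at -1.71 and Hox genes at -0.745. Quantile normalisation on top turned activated microglia to -0.515, complement to -0.0201, MHC class II to -0.257 and lipid handling to -0.179. It ended the calls of monocytes (0.495), reactive astrocytes (0.152), matrix (0.367) and cytokines (0.204). The genes were Arg1 at 4.82, Ngp at 4.50, Anpep at 4.05, Cd36 at 3.92, Col5a1 at 3.85, Myh4 at -4.83, Atp2a1 at -4.37, Glra1 at -3.40, Ebf3 at -3.40 and Tac2 at -3.23.

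Of the 2634 probes with no gene symbol, which no comparison of genes uses, some changed in every comparison. The numbers were 506, 221 and 205 at cerebral days 1, 3 and 7, 748, 432 and 766 at spinal days 1, 3 and 7, and 284, 234 and 581 for the differences at those days. They were 68 and 648 for day 7 against day 1 in cerebrum and cord, and 792 between the controls.

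The real split gave the largest count each time, 1 of 35 splits of 8 arrays or 1 of 100 drawn for the differences. These are too few splits to exclude chance. The highest other splits gave 3, 1 and 2 genes against the real 3341, 1149 and 1295 at cerebral days 1, 3 and 7, and 1994, 714 and 244 against 6224, 3742 and 6207 at spinal days 1, 3 and 7. They gave 1115, 423 and 2720 against 2200, 1808 and 5382 for the differences, 0 and 1 against 562 and 5391 for day 7 against day 1, and 674 against 6778 between the controls.

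Myelin genes were higher in the injured cerebrum than in cerebral controls at day 1 (mean log2 change 0.50). Low values in control replicates 3 and 4 alone stay open, since the change against controls 1 and 2 fell to 0.271 (camera p = 0.00296, and p = 0.267 with an estimated correlation). Striatum genes did not rise (-0.213), but more striatum in the injured samples stays open. Striatum scores of 0.591 to 0.786 at day 1 lay within the controls' 0.0636 to 1.5. More thalamus in the injured samples is a candidate explanation, since thalamus genes rose by 0.832 on average at day 1. The day 1 scores of 0.633 to 0.767 all lay above the controls' -0.719 to 0.499. Over the injured cerebral arrays of all days, the scores ran from 0.424 to 0.77. A different piece of tissue and an effect of the injury on myelin genes both stay open.

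Skeletal muscle genes were higher in the spinal controls than in the injured cord. The muscle score had an SD of 1.58 over the 4 controls, against 0.738 for the next list, Schwann cells, which may reflect muscle tissue in some control samples. The injury lowering muscle genes of the cord itself stays open, since 3 controls (3.62, 3.04 and 1.21) lay above and 1, at 0.236, within the range of the 12 injured arrays (-0.113 to 0.98).

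P2ry12, Siglech, Slc2a5 and Sall1 were lower in the cord at day 1, while Tmem119 and Olfml3 were higher. Dilution of resident cells by other RNA is argued against as the whole cause, since the 12 homeostatic genes changed with an SD of 0.914 against a median SE of 0.242, with 2 risen and 4 fallen. The scaling of the arrays is argued against, since P2ry12 stood at -1.93 at its nearest to 0 over 3 other scalings. A loss of some microglia, a change of their state under the injury and a batch that follows the groups stay open, and these could not be separated here.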

How the results depend on the processing

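Values as deposited, an exact offset, the allowance as a bound, median scaling, a robust prior alone and the settings with 2 controls were chosen after seeing the data. The values as deposited drop both the offset and the bound, every other setting changed 1 choice, and the cause of a change was not tested. Of 183 called list shifts, 23 kept their call with an estimated correlation and 160 lost it. Quantile normalisation on top left 159 the same, weakened 18 and turned 6. The robust prior left all 183 the same, median scaling and array weights 180 each, and 75th percentile scaling 178. Leaving out 1 array left 1804 list shifts the same and 52 past the threshold no more, and 1582 named genes the same and 18 weaker. Of 170 named genes, 170 kept their call under each of the 3 settings 75th percentile scaling, median scaling and array weights. The number was 168 under the robust prior, 167 under quantile normalisation and 163 in a fit of only the compared groups. All 12 counts stayed within 1.5 times under both scalings, the other probe rule and the robust prior. A filter on dim probes and an intensity trend, both planned, were not run, since centred values hold no intensity, and for the same reason signal over background cannot be given.

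With quantile normalisation on top, changed genes numbered 5256, 2403 and 2132 at cerebral days 1, 3 and 7, 2251 and 3464 at spinal days 3 and 7, 3239 for the day 7 difference, and 1665 and 1985 for day 7 against day 1 in cerebrum and cord. The likeness of the responses at day 7 was 0.529. The lists that turned were cell cycle at -0.278 and complement at -0.12 in the day 3 difference, and activated microglia at -0.515, complement at -0.0201, MHC class II at -0.257 and lipid handling at -0.179 in the day 7 difference. By construction this setting gives every array the same spread.

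In a fit of only the compared groups, which has fewer residual degrees of freedom, the counts were 2010 at spinal day 3, 955 for the day 3 difference and 1052 for cerebral day 7 against day 1, where array weights gave 1143. Values as deposited gave 3002 and 2290 at cerebral days 3 and 7, 6250 at spinal day 3 and 365 for cerebral day 7 against day 1, where matrix genes turned to -0.0162. The offset taken as exact, which removes the bound, gave 3888 and 4340 at cerebral days 3 and 7, 7470 and 9754 at spinal days 3 and 7, and 2962 and 9661 for day 7 against day 1. The allowance as a bound gave 828 and 3564 for the day 3 and day 7 differences. Cerebral controls 3 and 4 only gave 2115 at cerebral day 1. Cerebral controls 1 and 2 only gave 1719, 590 and 741 at cerebral days 1, 3 and 7, and 1056 and 873 for the day 1 and day 3 differences, with fewer arrays. Leaving out 1 array moved cerebral day 7 against day 1 to between 316, without cerebral day 7 replicate 2, and 449, without cerebral day 7 replicate 4.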

Other observations

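The gene families here were chosen after seeing the data, and their p-values are adjusted over all families and comparisons. Of 5 Fc gamma receptors, which bind antibodies on myeloid cells, 4 were higher at cerebral days 1, 3 and 7 (mean log2 change 1.18, 1.45 and 1.68, adjusted p = 0.0274 with an estimated correlation at each day). In the cord 4, 4 and 5 were higher (1.55, 2.19 and 3.45, adjusted p = 0.0555, 0.0274 and 0.0274 with an estimated correlation). The families kept these directions under all 3 other scalings.

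Of 22 glutamate receptor subunits, 11, 11 and 15 fell at spinal days 1, 3 and 7 (mean log2 change -0.40, -0.73 and -1.05, or -0.302, -0.459 and -0.49 at the nearest to 0 over the other scalings, adjusted p = 0.326, 0.156 and 0.158 with an estimated correlation). Neuron scores fell too, from -0.309 in control to -0.672, -0.924 and -1.71. Of 46 genes of mitochondrial respiratory complex I, 38 had a negative spinal-minus-cerebral difference at day 7 and 0 a positive one (-0.615, adjusted p = 4.55e-16, and adjusted p = 0.0555 with an estimated correlation), beside neurons at -1.23. Complex I stood at 0.21 in the cerebrum (1 higher, 0 lower) and -0.405 in the cord (1 higher, 26 lower). Of 16 tubulins, 8 rose in each tissue at day 1 (0.40 and 0.50, adjusted p = 0.0558 and 0.0563 with an estimated correlation). These directions too held under the other scalings.

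Of 1091 olfactory receptors, 202 fell and 1 rose at cerebral day 1 (mean log2 change -0.191, or -0.256 to -0.159 over other scalings, adjusted p = 1.86e-10, or 0.0274 with an estimated correlation). At days 3 and 7, 60 and 29 fell and 0 rose in the cerebrum (-0.216 and -0.18). In the cord 49 and 82 fell and 1 and 2 rose (-0.173 and -0.19). Adjusted p was 0.0274, 0.0563, 0.175 and 0.243 with an estimated correlation. At spinal day 1, 52 rose and 47 fell (0.0057, or -0.0214 to -0.0188 over other scalings). The cerebral falls share 4 controls, and spinal controls lay below these (8 higher, 126 lower). No cause was tested.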
